A study of Mus musculus with 21 samples.

How the data were processed

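Tuft cells were sorted from the thymi of young male mice, and RNA was profiled by bulk MARS-seq, a 3′ end method that tags each captured molecule with a UMI. Thymi were dissociated with Liberase TH and DNase, cells were sorted into lysis buffer, and polyadenylated RNA was taken up on Dynabeads, per the labels. Untreated WT mice gave 5 libraries, WT mice 18 h and 3 d after intraperitoneal dexamethasone (200 µg per 10 g of body weight) gave 3 and 5, and Il13ra1 WT and KO mice 6 d after the same treatment gave 4 each. The number in a sample's description differs from that in its title for 18 h replicate 3. For WT replicate 2 and KO replicate 1 at 6 d the description carries a pair of digits instead. The title numbers are used here.

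The deposited tables hold UMI counts per gene, as counts before any scaling, in columns marked as raw per the file headers. Beside them the authors give a log2 fold change and an adjusted p-value per gene for each comparison. Both deposited statistics, the log2 fold change and the p-value, were only set beside the values computed here. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq, DESeq2 and the mouse genome mm10, without settings. A further 42 per-sample columns of scaled values from the authors were not used here, and 0 raw count columns were left without a sample. The tables list 11582 genes (time course) and 11618 genes (Il13ra1), and every listed gene reaches at least 6 counts in some library of its table, so genes under that level are not listed.

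Depth ranged from 212512 to 1213151 UMIs per library: 278098 to 497372 in untreated, 332341 to 650055 at 18 h, 212512 to 546540 at 3 d, 735895 to 1213151 in WT at 6 d and 434655 to 920116 in KO. Between 10560 and 11496 genes had a UMI in a library, and the 10 highest genes took 4.56 to 7.42 percent of the counts. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 1.68 to 7.60 between pairs.

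Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each table was fitted apart, since the tables were counted in separate runs, with TMM scaling, filterByExpr (minimum count 5, minimum total 15), robust quasi-likelihood fits and two-sided tests. The 3 time course groups shared a single estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called; 9980 and 9649 genes were tested. The common biological coefficient of variation was 0.205 and 0.258. Levels are CPM values from edgeR, UMI counts scaled by the TMM-adjusted library sizes, given as mean and SD over libraries, and fold changes are edgeR estimates with their SE. Every fold change has the later time point or the KO first.

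Before the data were examined, the comparisons, the tests, 27 gene lists, most alternatives and the rule for naming genes were fixed. That rule names, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall among genes at or above the median average log2 CPM, leaving out predicted, ribosomal and mitochondrial names. It adds up to 4 called members of each list with the smallest adjusted p, or the 2 with the highest counts where none was called. It also adds 16 genes in every comparison: Il13ra1, Il4ra, Stat6, Il25, Pou2f3, Trpm5, Dclk1, Avil, Alox5, Alox5ap, Ltc4s, Hpgds, Ptgs1, Chat, Fkbp5 and Tsc22d3.

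Of the 27 lists, 26 had measured members; the list of mitochondrially encoded transcripts had none. Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison by Benjamini-Hochberg, and again with an estimated correlation. With the preset correlation 12, 13, 6 and 9 lists were called at 18 h, at 3 d, between 18 h and 3 d, and in KO. With an estimated correlation 0, 0, 0 and 1 were, the last being the taste list. Sums of marker lists for other cells were compared by exact permutation of the libraries.

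Symbols were matched to GENCODE vM21 on mm10: 11398 of the time course symbols directly and 177 through RefSeq or older names, 7 without a match, and 11431, 178 and 9 in the Il13ra1 table. Reads of near-identical genes (Hspa1a and Hspa1b, Mt1 and Mt2, Cxcl1, Cxcl2 and Cxcl3) may be shared between them. Il13ra1 lies on chromosome X from 36112110 to 36171259 on the plus strand, and its last of 11 exons starts at 36168814.

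The authors' deposited adjusted p was under 0.05 for 69 genes at 18 h, 215 at 3 d, 99 between 18 h and 3 d, and 514 in KO. Of these, 53, 167, 63 and 445 were also called here. All had the same direction after the deposited log2 fold changes, named with the control or earlier group first, were reversed in sign. Tested on simulated data with the depth and spread of these libraries, the edgeR procedure recovered 71.2 percent of 4-fold changes at 18 h, 80.3 percent at 3 d, 65.2 percent between 18 h and 3 d, and 80.3 percent in KO. For 2-fold changes the shares were 29.9, 38.8, 26.9 and 17.9 percent, and false calls numbered 7 of 80, 11 of 98, 6 of 72 and 4 of 71.

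Alternatives to TMM were edgeR's RLE (relative log expression) size factors and library size alone. Other tests were DESeq2 1.42.0 and limma-voom with quality weights. A stricter and no count filter, counts thinned to equal depth and a 2-fold threshold were also tried. Further alternatives took replicate numbers as a block, used only the compared groups or left out each library in turn. A call described as lost without any of several libraries was lost when each of them alone was left out. Chosen after seeing the data were leaving out the pair of libraries with the fewest UMIs, a thymocyte marker covariate and, for KO, 1 surrogate variable from sva 3.50.0. Libraries of equal replicate number in different groups correlated with r from −0.04 to 0.18 over 11 pairs, and from −0.57 to −0.21 over 4 pairs. Libraries of unequal number reached an r of 0.138 in the time course and 0.589 among the Il13ra1 libraries. The numbers thus gave no pairing, and samples were treated as unpaired. A pairing or batch not marked by the numbers was not tested. Similarity of responses was measured by Pearson's r of log2 fold changes across genes, beside simulated groups without change, split controls or relabelled libraries.

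For the thymocyte markers, the mean pairwise correlation of log2 CPM after subtracting group means was compared with 1000 random sets of as many genes of like level, drawn with a fixed seed. The same was done for the tuft identity list as a control. This comparison was added after the results, the correlation included, had been seen.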

Results

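RNA was measured in sorted tuft cells from the thymus of young male mice by bulk MARS-seq, which counts unique molecular identifiers (UMIs) at the 3′ end of polyadenylated transcripts. Tuft cells of the thymus are epithelial cells of the medulla that carry taste-signalling proteins and release IL-25. Dexamethasone, a synthetic glucocorticoid that depletes thymocytes and shrinks the thymus, was injected at 200 µg per 10 g of body weight. Libraries came from untreated wild-type (WT) mice (n = 5) and from WT mice 18 h (n = 3) or 3 d (n = 5) after the injection. A separately counted table held Il13ra1 knockout (KO) and WT mice 6 d after the injection (n = 4 each). The labels do not state that replicates are separate animals, so p-values measure only the spread between these samples.

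At 18 h, Serpina3n, Cxcl1 and Bag3 rose and Tnni3 and Alox12e fell. Serpina3n, which encodes an acute-phase protease inhibitor, was 15.9-fold higher than in untreated cells (216 ± 139 against 13.3 ± 3.59 CPM, SD, n = 3 and 5). Cxcl1, a neutrophil attractant, rose 3.84-fold (279.5 ± 49.7 against 71.7 ± 22.95 CPM, SD, n = 3 and 5), and Bag3, a partner of heat-shock proteins, rose 3.61-fold (234 ± 60.3 against 65.1 ± 15.4 CPM). With edgeR the Benjamini-Hochberg adjusted p was 2.3e-07 for Serpina3n, 0.00102 for Cxcl1 and 1.3e-06 for Bag3. Tnni3, a troponin subunit, was 2.83-fold lower, and Alox12e, a lipoxygenase of stratified epithelium, fell by 1.43 ± 0.19 (SE) on the log2 scale. In all, 72 of 9980 tested genes passed, 54 higher and 18 lower, and 961 had an unadjusted p under 0.05. Without 18 h replicate 2, 32 genes passed, with limma-voom 44, and with a thymocyte marker covariate, chosen after seeing the data and different between the groups, 23.

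The apolipoprotein gene Apoa4 rose 3.30-fold at 18 h (215 ± 100.3 against 62.9 ± 14.5 CPM, SD, n = 3 and 5; edgeR, Benjamini-Hochberg adjusted p = 0.00644). Lcn2, which encodes an iron-scavenging lipocalin, rose 6.85-fold (1191 ± 610.1 against 174 ± 81.8 CPM, edgeR, Benjamini-Hochberg adjusted p = 0.0128). Dclk1, a kinase gene widely used as a tuft cell marker, fell by 1.19 ± 0.25 (SE) on the log2 scale, from 124 ± 26.1 to 57.1 ± 20.9 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.00771). Lcn2 and Dclk1 did not pass without 18 h replicate 2, and their highest edgeR, DESeq2 or limma adjusted p (Benjamini-Hochberg) over all alternatives was 0.233 and 0.217. Krt77, a keratin of differentiated epidermis, and Gsta2, a glutathione transferase gene, fell by 2.07 and 1.75 on the log2 scale and also did not pass without that library.

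Of 28 glucocorticoid-responsive genes, 5 rose at 18 h, 0 fell and 23 were not called; adjusted over the list alone, 15 were higher and 1 lower. The 5 were Lcn2, Mt1, Mt2 (metallothioneins with similar sequences), Per1 (a clock gene) and Txnip (a brake on glucose uptake). Camera placed the list higher than other genes (Benjamini-Hochberg adjusted p = 9.0e-08), with a median log2 fold change of 0.63 (adjusted p = 0.141 with an estimated correlation). Lcn2, Mt1, Mt2, Per1 and Txnip each lost their call without 18 h replicate 2, and Mt2 also without any of 7 other libraries. The widely used glucocorticoid targets Fkbp5 and Tsc22d3 were 2.87-fold and 1.85-fold higher but did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.238 and 0.0604). Fkbp5 passed with DESeq2 and without 18 h replicate 1, and Tsc22d3 in 5 settings, DESeq2 among them (lowest edgeR, DESeq2 or limma adjusted p 4.5e-04 and 0.00182, Benjamini-Hochberg). Fkbp5 read 128 ± 87.1 CPM at 18 h and 46.9 ± 19.6 CPM in untreated cells (SD, n = 3 and 5).

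Of 28 immediate early and dissociation-responsive genes, 7 rose at 18 h, 0 fell and 21 were not called; adjusted over the list alone, 13 were higher (camera, Benjamini-Hochberg adjusted p = 3.2e-12; adjusted p = 0.120 with an estimated correlation). Among the 7 were 5 of 5 chaperone genes and 1 of 18 immediate early genes. The chaperone genes Dnajb1, Hsph1 and Hspb1 rose 2.42-fold, 2.40-fold and 1.97-fold, and their highest Benjamini-Hochberg adjusted p over the edgeR, DESeq2 and limma alternatives was 1.2e-04, 1.6e-04 and 9.1e-05. Hspb1 went from 2128 ± 178 to 4187 ± 359 CPM (SD, n = 5 and 3). The transcription factor gene Atf3 rose 1.94-fold, from 660.2 ± 96.2 to 1279 ± 275 CPM.

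Tuft cell genes other than Dclk1 were not called at 18 h. Of 46 tuft identity genes, 45 were not called, and the list median was 0.05 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 0.575). Trpm5, the cation channel of taste signalling, read 2711 ± 181 CPM at 18 h and 2177 ± 363 CPM in untreated cells, and Avil, an actin-binding tuft marker, read 3019 ± 312 and 2679 ± 419 CPM (SD, n = 3 and 5). None of the 19 taste genes, 14 secreted effector and eicosanoid genes or 27 IL-4 and IL-13 signalling genes was called by edgeR, and camera's Benjamini-Hochberg adjusted p was 0.864, 0.899 and 0.116. Il25 was 1.12-fold higher at 18 h, not called (edgeR, Benjamini-Hochberg adjusted p = 0.873).

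Antigen presentation genes of MHC class II were lower as a group at 18 h. None of 13 members was called by edgeR, 4 were lower when adjusted over the list alone, and the median log2 fold change was −0.56 (camera, Benjamini-Hochberg adjusted p = 1.1e-04; adjusted p = 0.187 with an estimated correlation). H2-Ab1, the beta chain of I-A, read 1201 ± 152 CPM against 1727 ± 319 CPM in untreated cells (SD, n = 3 and 5). Markers of macrophages and dendritic cells, which carry MHC class II, had a median of −0.83 on the log2 scale, with 14 of 17 negative, and the chemokine receptor gene Ccr7 fell by 2.19 ± 0.56 (SE) on the log2 scale. Ccr7 lost its call without any of 9 libraries, all 18 h libraries included (highest edgeR, DESeq2 or limma adjusted p 0.555, Benjamini-Hochberg). The 20 MHC class I genes were not called as a group (camera, Benjamini-Hochberg adjusted p = 0.235). Of 42 interferon-stimulated genes, 1 rose, the antiviral gene Rsad2 (2.23-fold), and 12 were higher and 1 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.2e-06; adjusted p = 0.141 with an estimated correlation).

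Among housekeeping groups at 18 h, camera placed 76 ribosomal protein genes (median −0.17 on the log2 scale) and 20 cell cycle genes (median −0.35) lower, with 0 members called by edgeR (Benjamini-Hochberg adjusted p = 5.1e-05 and 0.00354; adjusted p = 0.474 and 0.394 with an estimated correlation). Glycolysis and hypoxia genes and unfolded protein response genes were placed higher (camera, Benjamini-Hochberg adjusted p = 0.00228 and 0.00847; adjusted p = 0.212 and 0.175 with an estimated correlation). Slc2a1, the main glucose importer, rose 1.89-fold and Herpud1, a degradation factor of the endoplasmic reticulum, rose 1.62-fold. Herpud1 lost its call without 18 h replicate 2 or 3. Sesn1, a stress-induced p53 target, rose 2.61-fold but lost its call without any of 7 libraries (highest edgeR, DESeq2 or limma adjusted p 0.542, Benjamini-Hochberg), and the p53 list was not called (camera, Benjamini-Hochberg adjusted p = 0.0876). Lists for oxidative phosphorylation, cholesterol synthesis and thymus growth factors were not called (camera, Benjamini-Hochberg adjusted p = 0.145, 0.899 and 0.235).

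Marker genes of thymocytes moved in the same libraries. Of 20 thymocyte and T cell genes, Themis, needed for T cell selection, fell, 12 were lower when adjusted over the list alone, and the median log2 fold change was −1.82 (camera, Benjamini-Hochberg adjusted p = 2.8e-09; adjusted p = 0.249 with an estimated correlation). Themis lost its call without untreated replicate 1 or 3 or 18 h replicate 1 or 2, and with DESeq2 or limma-voom (highest adjusted p 0.705, Benjamini-Hochberg). The summed level of the list was 327 ± 122 CPM at 18 h and 1049.9 ± 837 CPM in untreated cells (SD, n = 3 and 5; exact permutation p = 0.125). Endothelial and fibroblast markers were placed higher (camera, Benjamini-Hochberg adjusted p = 0.00218 and 0.0118; adjusted p = 0.474 for both with an estimated correlation). Markers of other mimetic epithelium were placed lower (camera, Benjamini-Hochberg adjusted p = 0.0148; adjusted p = 0.197 with an estimated correlation). Lists for macrophages and dendritic cells, B cells, innate lymphoid cells, cortical epithelium and medullary epithelium were not called (camera, Benjamini-Hochberg adjusted p = 0.0616, 0.899, 0.374, 0.899 and 0.899).

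**Figure D1:**
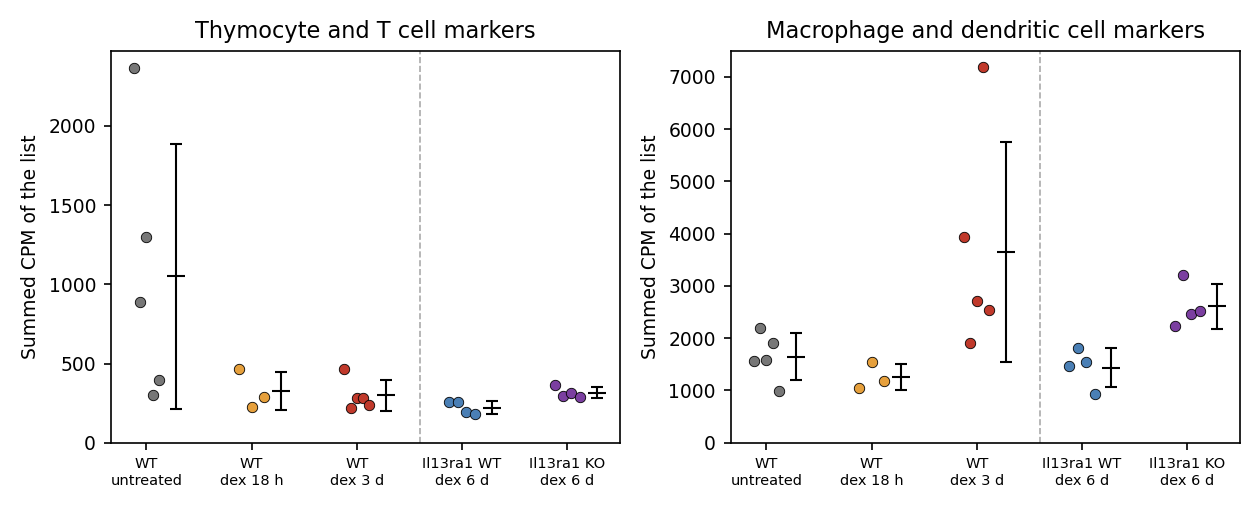
Summed level (CPM) of thymocyte and T cell markers and of macrophage and dendritic cell markers in each library of the 5 groups. Points are libraries, bars give mean ± SD, and the dashed line separates the tables, which were normalized apart.

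At 3 d, Psca, Lcn2 and Ltf rose and Lipc fell. Psca, a surface antigen of epithelia, rose 9.67-fold (507 ± 292 against 53.1 ± 37.0 CPM, SD, n = 5 each), Lcn2 rose 7.77-fold and Ltf, which encodes lactoferrin, rose 7.48-fold. Their Benjamini-Hochberg adjusted p with edgeR was 0.0101, 0.00318 and 0.00788. Apoc1, an apolipoprotein gene, rose 5.51-fold and Cxcl3, a neutrophil attractant, rose 4.73-fold (edgeR, Benjamini-Hochberg adjusted p = 1.1e-05 and 8.3e-04). Lipc, which encodes hepatic lipase, fell by 1.39 ± 0.14 (SE) on the log2 scale, from 560 ± 115 to 213 ± 21.7 CPM (edgeR, Benjamini-Hochberg adjusted p = 2.1e-08). In all, 204 of 9980 genes passed, 159 higher and 45 lower, and 1304 had an unadjusted p under 0.05. Without 3 d replicate 4, 131 passed, and with the thymocyte marker covariate 61.

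Cldn4 and Cldn3, which encode tight junction proteins, rose 2.15-fold and 1.62-fold at 3 d (edgeR, Benjamini-Hochberg adjusted p = 2.4e-06 and 3.1e-04). Lyz1, a lysozyme gene, and Pcolce2, a collagen-processing enhancer, fell by 1.39 and 1.08 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.00353 and 0.00147). Apod, a lipid carrier, rose 13.6-fold (136 ± 87.8 against 10.2 ± 4.93 CPM, SD, n = 5 each; edgeR, Benjamini-Hochberg adjusted p = 0.0245). Apod lost its call without any of untreated replicates 1, 3, 4 and 5 or without 3 d replicate 1, and its highest adjusted p over the edgeR, DESeq2 and limma alternatives was 0.249 (Benjamini-Hochberg).

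Glucocorticoid-responsive genes were also higher as a list at 3 d, with partly other members than at 18 h. Of 28, 8 rose, 0 fell and 20 were not called; adjusted over the list alone, 12 were higher, with a median log2 fold change of 0.66 (camera, Benjamini-Hochberg adjusted p = 4.8e-11; adjusted p = 0.0662 with an estimated correlation). Anxa1, an anti-inflammatory phospholipid-binding protein, rose 1.89-fold (2464 ± 350.1 against 1299 ± 123 CPM, SD, n = 5 each), Nfkbia, the NF-κB inhibitor, rose 1.56-fold and Per1 rose 2.03-fold. At 18 h Anxa1 and Nfkbia read 1394 ± 190 and 1386 ± 96.0 CPM (SD, n = 3) and were not called against untreated. Fkbp5 and Tsc22d3 did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.578 and 0.761).

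Of 28 immediate early and dissociation-responsive genes, 13 rose at 3 d, 0 fell and 15 were not called; adjusted over the list alone, 20 were higher (camera, Benjamini-Hochberg adjusted p = 8.2e-12; adjusted p = 0.0662 with an estimated correlation). Among the 13 were 4 of 5 chaperone genes and 7 of 18 immediate early genes. Atf3 rose 1.96-fold (1292 ± 64.9 against 660.2 ± 96.2 CPM, SD, n = 5 each), Hspb1 1.54-fold, Ier2 1.52-fold and Ier3 1.71-fold. Ddit3, the CHOP factor of the unfolded protein response, rose 2.11-fold. With Herpud1 and Xbp1, the latter not called without untreated replicate 5 or 3 d replicate 4, it made 3 of 24 unfolded protein response genes that rose (camera, Benjamini-Hochberg adjusted p = 0.00631; adjusted p = 0.138 with an estimated correlation).

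Taste-signalling genes were lower at 3 d. Of 19, 0 rose, 2 fell and 17 were not called; adjusted over the list alone, 4 were lower, with a median log2 fold change of −0.41 (camera, Benjamini-Hochberg adjusted p = 0.00965; adjusted p = 0.397 with an estimated correlation). Gng13 and Gnb3, the G protein subunits of taste transduction, fell by 0.44 ± 0.10 and 0.39 ± 0.10 (SE) on the log2 scale. Gng13 lost its call without untreated replicate 5 or 3 d replicate 4, and Gnb3 without untreated replicate 3, 4 or 5 or 3 d replicate 1 or 2; their highest edgeR, DESeq2 or limma adjusted p over all alternatives was 0.0628 and 0.0872 (Benjamini-Hochberg). Of 46 tuft identity genes, 1 rose (Krt8, a keratin) and 3 fell (Gnb3, Gng13 and Nrep); Krt8 and Nrep each lost their call without any of 7 libraries, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.445). Il25, the cytokine by which tuft cells activate type 2 lymphocytes, was 1.54-fold higher, not called (707 ± 111 against 461 ± 138 CPM, SD, n = 5 each; edgeR, Benjamini-Hochberg adjusted p = 0.0558). Il25 passed in 10 of 24 other settings, DESeq2 and limma-voom among them (lowest adjusted p 0.00506, Benjamini-Hochberg).

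Of 14 secreted effector and eicosanoid genes, 0 were called by edgeR at 3 d (camera, Benjamini-Hochberg adjusted p = 0.0959), and of 27 IL-4 and IL-13 signalling genes 1 fell, the eotaxin gene Ccl11 (camera, Benjamini-Hochberg adjusted p = 0.924). Ccl11 lost its call without any of 8 libraries, each 3 d library included (highest edgeR, DESeq2 or limma adjusted p 0.191, Benjamini-Hochberg). Il13ra1 read 68.2 ± 16.3 CPM at 3 d and 64.0 ± 13.3 CPM in untreated cells (SD, n = 5 each). Among 42 interferon-stimulated genes, Isg20, Irf1 and Ifit1 rose and Ifi27l2a fell (camera, Benjamini-Hochberg adjusted p = 0.0294; adjusted p = 0.397 with an estimated correlation). Ifit1 lost its call without any of 7 libraries. Hbegf and Vegfa, growth factor genes, rose 2.11-fold and 1.63-fold among 24 thymus growth factors, a list that was not called (camera, Benjamini-Hochberg adjusted p = 0.0676).

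Camera placed ribosomal protein, oxidative phosphorylation, cell cycle and cholesterol synthesis genes lower at 3 d (Benjamini-Hochberg adjusted p = 0.00314, 0.00314, 0.00631 and 0.0194; adjusted p = 0.541, 0.423, 0.397 and 0.138 with an estimated correlation). Medians were small for the first pair, −0.12 for 76 ribosomal and −0.13 for 80 oxidative phosphorylation genes on the log2 scale. Rpl36a, a ribosomal protein gene, and Cox7c, a subunit of cytochrome oxidase, fell by 0.61 and 0.53 on the log2 scale. Of 20 glycolysis and hypoxia genes, Slc2a1 (1.79-fold) and Vegfa rose. Eno1, a glycolytic enzyme gene of the same list, fell by 0.60 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0178). Rpl36a lost its call without untreated replicate 3 or 3 d replicate 4, and Cox7c without untreated replicate 5 or 3 d replicate 4. Glycolysis, p53, MHC class I and MHC class II lists were not called (camera, Benjamini-Hochberg adjusted p = 0.0580, 0.445, 0.166 and 0.427).

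Markers of other cells also differed at 3 d. Macrophage and dendritic cell markers summed to 3656 ± 2107 CPM against 1649 ± 447 CPM in untreated cells (SD, n = 5 each; exact permutation p = 0.0159, Benjamini-Hochberg adjusted p = 0.0476 over 9 marker lists), and Cd14, the endotoxin co-receptor, rose 3.96-fold. The list was placed higher (camera, Benjamini-Hochberg adjusted p = 2.1e-04; adjusted p = 0.298 with an estimated correlation). Thymocyte markers summed to 298 ± 97.2 CPM (exact permutation p = 0.0397, Benjamini-Hochberg adjusted p = 0.0893) and 0 of 20 were called by edgeR, with 11 lower when adjusted over the list alone. That list was placed lower (camera, Benjamini-Hochberg adjusted p = 2.9e-09; adjusted p = 0.295 with an estimated correlation).

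The B cell and innate lymphoid lists were placed higher at 3 d (camera, Benjamini-Hochberg adjusted p = 0.0294 and 0.0470; adjusted p = 0.180 and 0.196 with an estimated correlation). B cell markers summed to 1269 ± 169 CPM against 867 ± 82.8 CPM in untreated cells, and innate lymphoid markers to 373 ± 18.5 against 247 ± 27.7 CPM (SD, n = 5 each; exact permutation p = 0.00794, Benjamini-Hochberg adjusted p = 0.0357 over 9 marker lists, for each). Their called members were Ly6d (1.48-fold) and Il17rb, the IL-25 receptor (1.51-fold), genes that thymic epithelium and tuft cells also express. Ly6d read 999.5 ± 180 CPM at 3 d against 679 ± 113 CPM in untreated cells, and Il17rb 314 ± 21.8 against 206 ± 42.5 CPM. Ly6d and Il17rb made up most of their sums, which therefore do not show a rise of those cells. Lists for fibroblasts, endothelium, cortical epithelium, medullary epithelium and other mimetic epithelium were not called (camera, Benjamini-Hochberg adjusted p = 0.445, 0.235, 0.193, 0.445 and 0.924).

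Between 18 h and 3 d, Pigr, Gabrp and Vnn3 rose while Apoa4 and Serpina3n fell. Pigr, which carries IgA across epithelium, rose 5.04-fold (383 ± 99.4 against 76.2 ± 18.2 CPM, SD, n = 5 and 3; edgeR, Benjamini-Hochberg adjusted p = 2.1e-06). Gabrp, a GABA receptor subunit, rose 9.22-fold and Vnn3, a pantetheinase, 4.21-fold. Apoa4 fell by 3.19 ± 0.36 (SE) on the log2 scale, to 21.4 ± 13.1 CPM, and Serpina3n fell by 2.98 ± 0.33 (SE) on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 3.7e-05 and 9.2e-06). Krt77 and Gsta2, low at 18 h, were 4.45-fold and 4.39-fold higher at 3 d. In all, 73 of 9980 genes passed, 45 higher and 28 lower, and 871 had an unadjusted p under 0.05; with replicate numbers as a block, 114 passed.

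Of 5 chaperone genes, 3 fell from 18 h to 3 d. Hsph1 fell by 0.76 ± 0.14 (SE) on the log2 scale and Dnajb1, which lost its call without 18 h replicate 2, by 0.71 ± 0.14 (SE) on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.00250 and 0.00344). Hspa1b, the third, lost its call without any of 5 libraries and with limma-voom. The immediate early and dissociation-responsive list as a whole was not called (camera, Benjamini-Hochberg adjusted p = 0.724), nor was the glucocorticoid list (0.437), in which Anxa1 and Nfkbia rose, the latter not called without 18 h replicate 3 or 3 d replicate 2. Serpinb2, a protease inhibitor, and Alox15, a lipoxygenase, rose 2.66-fold and 2.59-fold (Alox15 not called without any single 18 h library or 3 d replicate 2) among 27 IL-4 and IL-13 signalling genes (camera, Benjamini-Hochberg adjusted p = 0.238).

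Macrophage and dendritic cell markers were placed higher at 3 d than at 18 h, with Cd14 and Itgam risen, 15 not called and 10 higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 9.5e-09; adjusted p = 0.237 with an estimated correlation). Cd14 and Itgam lost their calls without any single 18 h library, and Itgam also without 4 others. Taste genes were placed lower and MHC class II genes higher (camera, Benjamini-Hochberg adjusted p = 0.00809 for both; adjusted p = 0.449 and 0.373 with an estimated correlation). MHC class I and other mimetic epithelium were placed higher and cholesterol synthesis lower (camera, Benjamini-Hochberg adjusted p = 0.0224, 0.0235 and 0.0235; adjusted p = 0.304, 0.304 and 0.237 with an estimated correlation). The other 20 lists were not called. Tuft identity genes had 0 of 46 called by edgeR (camera, Benjamini-Hochberg adjusted p = 0.941).

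The responses at 18 h and 3 d shared 28 genes called higher in both and 4 called lower in both, where independent calls would share 0.860 and 0.0812. With the untreated libraries split so that the contrasts shared none, 1 to 11 genes were higher in both and 0 to 2 lower in both. Lcn2, Cxcl1, Atf3 and Hspb1 were among those higher in both, and Tnni3 among those lower in both. Apoa4 (higher, then lower) and Pigr (lower, then higher) were called in opposite directions, but the fall of Apoa4 at 3 d lost its call without any of 9 libraries, and with limma-voom (highest edgeR, DESeq2 or limma adjusted p 0.191, Benjamini-Hochberg). Across 9980 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.472. Both responses share the untreated libraries: 20 simulations without any change gave a mean r of 0.422 and a highest r of 0.457. The simulations drew each gene independently, whereas 76 ribosomal protein genes had a mean pairwise correlation of 0.297 within groups. The simulated spread of r may thus be too narrow to judge the observed r. In the split contrasts, which had 2 or 3 untreated libraries each, r averaged 0.146 (0.0806 to 0.201 over 20 splits).

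**Figure D2:**
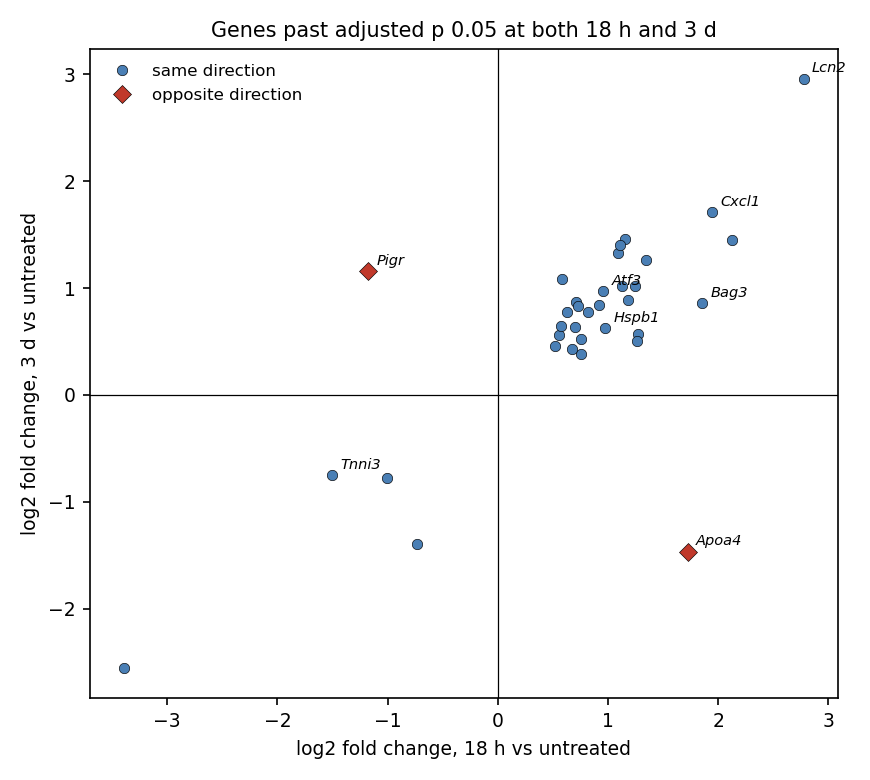
Log2 fold change against untreated at 18 h (horizontal) and at 3 d (vertical) for genes with an edgeR adjusted p under 0.05 at both times. Diamonds mark genes changed in opposite directions; both axes share the untreated libraries.

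Il13ra1, the receptor chain shared by IL-4 and IL-13, read 4.76, 4.17, 17.7 and 13.5 CPM in KO replicates 1 to 4 (4, 3, 10 and 5 UMIs). In WT replicates 1 to 4 of the same table it read 95.7, 53.6, 38.4 and 48.6 CPM. It fell by 2.66 ± 0.42 (SE) on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 5.1e-04). In the other table it read 64.1, 61.2, 64.1, 84.0 and 46.6 CPM in untreated, 72.2, 64.7 and 65.2 CPM at 18 h, and 89.2, 51.9, 80.2, 53.7 and 65.9 CPM at 3 d. The labels do not give what the knockout removes, and counted 3′ tags may lie outside it.

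In KO tuft cells 6 d after dexamethasone, Gnb3 and Il25 were lower, and Psca and the chaperone gene Hspb1 were higher. Gnb3 fell by 1.72 ± 0.23 (SE) on the log2 scale, from 1791 ± 422 to 544 ± 28.3 CPM (SD, n = 4 each; edgeR, Benjamini-Hochberg adjusted p = 1.5e-04). Il25 fell by 0.997 ± 0.247 (SE) on the log2 scale, from 1286 ± 152 to 647 ± 249 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0190). Psca rose 6.11-fold (2414 ± 467 against 396 ± 264 CPM, SD, n = 4 each; edgeR, Benjamini-Hochberg adjusted p = 0.00123). Hspb1 rose 4.87-fold (13655 ± 4639 against 2803 ± 799 CPM; edgeR, Benjamini-Hochberg adjusted p = 1.5e-04). Il25 lost its call without WT replicate 3 or KO replicate 1, 2 or 3, with a highest adjusted p over the edgeR, DESeq2 and limma alternatives of 0.0844 (Benjamini-Hochberg).

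Of 9649 genes, 481 passed, 343 higher and 138 lower in KO, and 1431 had an unadjusted p under 0.05; without WT replicate 4, 301 passed, and with replicate numbers as a block 241 (186 higher, 55 lower). Scaling by library size alone moved the median of all genes by −0.19 on the log2 scale and gave 220 higher and 253 lower, so the split between directions depends on the scaling. Prss53, a serine protease, and Fcgbp, a mucus protein, fell by 3.00 ± 0.30 and 2.79 ± 0.27 (SE) on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 9.6e-06 and 7.8e-06). Igsf8, a membrane protein, Lipc and Crym, a thyroid hormone-binding protein, fell by 2.44, 2.10 and 1.91 on the log2 scale. Emp1 and Mal, membrane proteins of epithelium, rose 8.15-fold and 7.15-fold, Crnn, of squamous epithelium, 6.93-fold, and Edn1, which encodes endothelin-1, 5.49-fold. Apoa4 read 0.943 ± 1.16 CPM in KO, under the level of 3 UMIs, and 19.8 ± 16.3 CPM in WT (SD, n = 4 each).

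Of 45 tuft identity genes, 0 rose, 11 fell and 34 were not called in KO; adjusted over the list alone, 18 were lower. The median log2 fold change was −0.52 (camera, Benjamini-Hochberg adjusted p = 1.6e-11; adjusted p = 0.0670 with an estimated correlation). Matk and Pik3r5, signalling proteins of tuft cells, fell by 1.40 ± 0.22 and 1.27 ± 0.20 (SE) on the log2 scale. Pou2f3, the master regulator of tuft cells, Trpm5 and Avil were 1.85-fold, 1.25-fold and 1.63-fold lower but did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.176, 0.580 and 0.0660). Avil passed in 4 other settings, DESeq2 and limma-voom among them, and Pou2f3 with 1 surrogate variable (lowest edgeR, DESeq2 or limma adjusted p 0.00229 and 0.0156, Benjamini-Hochberg).

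Of 10 taste genes, 0 rose, 5 fell and 5 were not called; adjusted over the list alone, 6 were lower, and the median log2 fold change was −0.97. Camera placed the list lower with its preset and its estimated correlation (Benjamini-Hochberg adjusted p = 2.5e-08 and 0.0219). The 5 were Gnb3, Tas1r1 and Tas1r3 (the umami receptor pair), Gng13 and Plcb2 (a phospholipase, chosen after its values were seen). All but Tas1r1 also belong to the tuft identity list, so the results of both lists are not separate evidence. Gng13 lost its call without WT replicate 2 or 3 or KO replicate 2, and Tas1r3 without KO replicate 2. Of 13 secreted effector and eicosanoid genes, Il25 fell and 12 were not called (camera, Benjamini-Hochberg adjusted p = 0.136). Ltc4s, which makes leukotriene C4, read 1271 ± 348 CPM in KO and 1369 ± 180.1 CPM in WT (SD, n = 4 each).

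**Figure D3:**
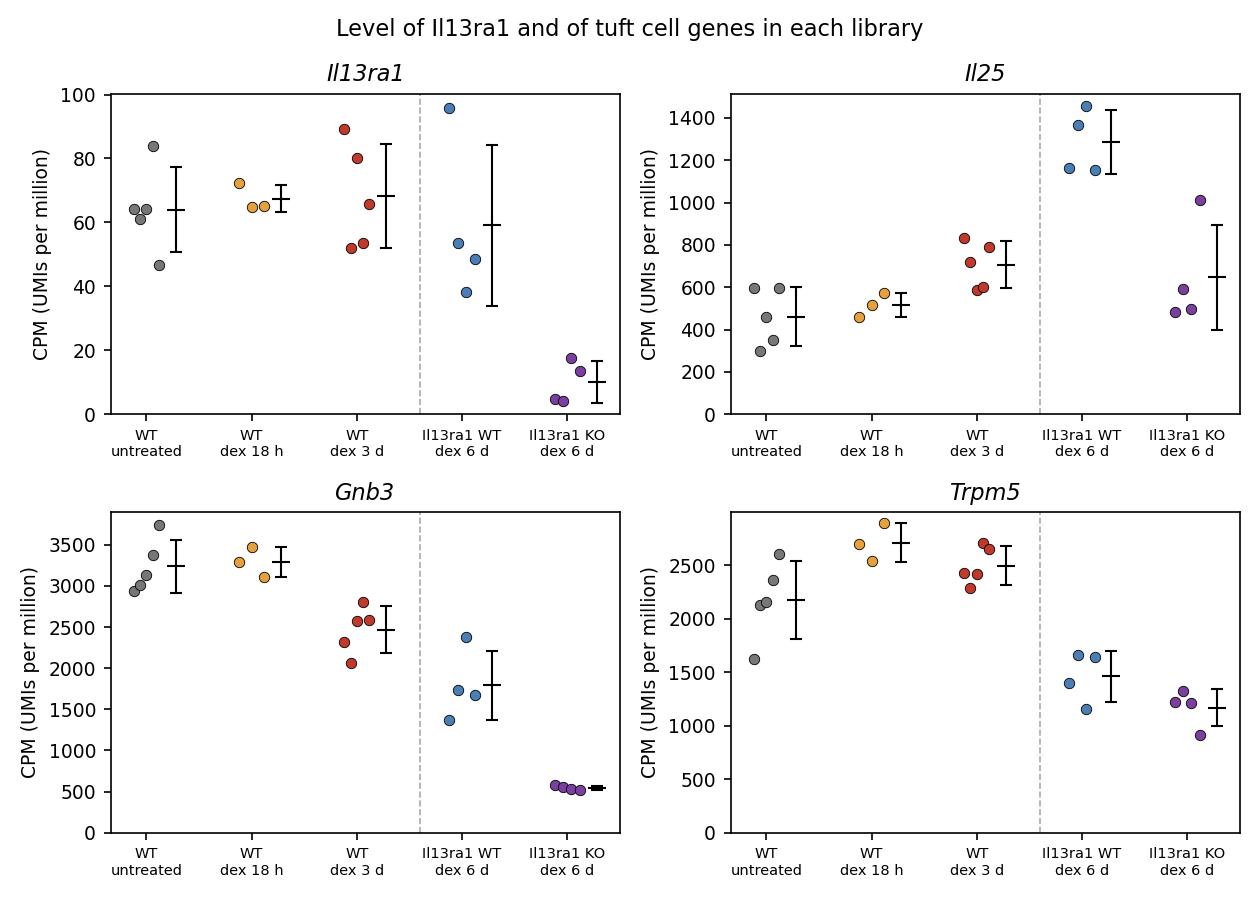
Level (CPM) of Il13ra1, Il25, Gnb3 and Trpm5 in each library of the 5 groups. Points are libraries, bars give mean ± SD, and the dashed line separates the tables, which were normalized apart.

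Among 25 IL-4 and IL-13 signalling genes, Arg1, the arginase gene, rose 3.25-fold and Serpinb2 1.99-fold (not called without WT replicate 1 or 4 or KO replicate 1), while Socs1, a feedback inhibitor of cytokine receptors, fell by 1.15 ± 0.25 (SE) on the log2 scale. Il13ra1 and the chemokine gene Ccl22 (chosen after its values were seen) also fell, 20 were not called, and the list as a whole was not called (camera, Benjamini-Hochberg adjusted p = 0.210). Il4ra and Stat6, the partner receptor and its transcription factor, did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.640 and 0.983).

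**Figure D4:**
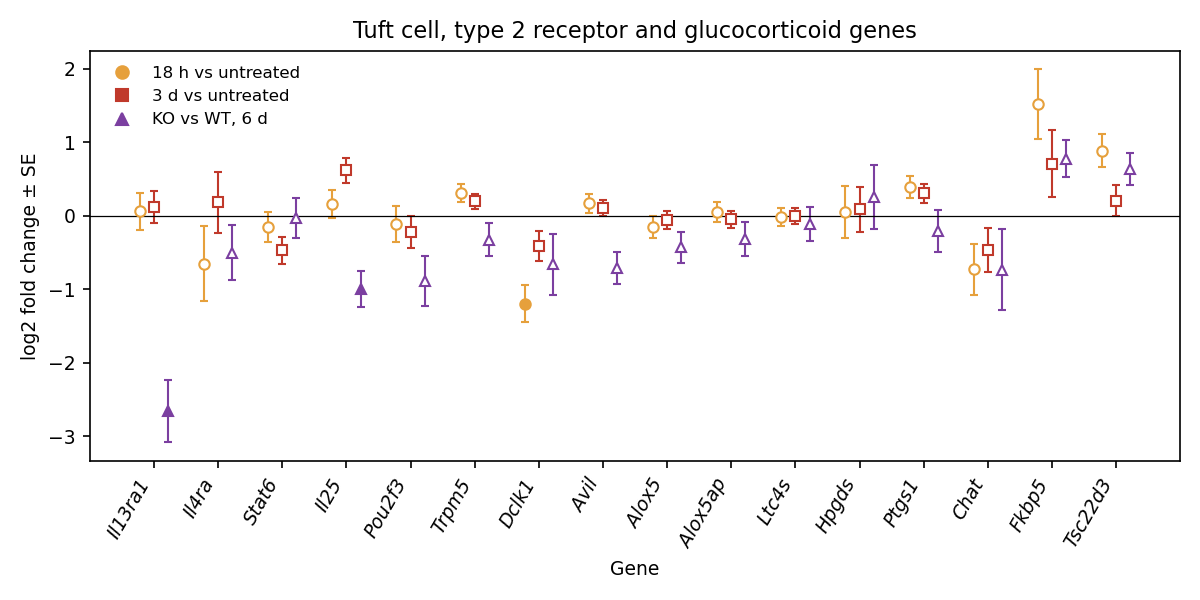
Log2 fold change ± SE of 16 genes named before the data were examined, at 18 h and 3 d against untreated and in KO against WT at 6 d. Filled symbols have an edgeR adjusted p under 0.05.

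Glucocorticoid-responsive genes were higher in KO: of 28, 12 rose, 0 fell and 16 were not called, and 16 were higher when adjusted over the list alone (median log2 fold change 0.85; camera, Benjamini-Hochberg adjusted p = 3.7e-10; adjusted p = 0.0599 with an estimated correlation). Ddit4, an mTOR inhibitor, rose 2.90-fold, Map3k6 2.74-fold, Errfi1, an EGF receptor inhibitor, 3.06-fold and Mt1 2.83-fold. Fkbp5 and Tsc22d3 were 1.72-fold and 1.56-fold higher but did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0748 and 0.0979). Of 28 immediate early and dissociation-responsive genes, 11 rose, 0 fell and 17 were not called, and 17 were higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.6e-11; adjusted p = 0.199 with an estimated correlation). Among the 11 were 5 of 5 chaperone genes and 4 of 18 immediate early genes. Hsph1 and Dnajb1 rose 3.30-fold and 2.77-fold, and the transcription factor gene Klf2 rose by 1.38 ± 0.27 (SE) on the log2 scale.

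Other mimetic epithelium, cells of the medulla that copy peripheral tissues, had 7 of 29 markers higher, 2 lower and 20 not called; adjusted over the list alone, 10 were higher and 3 lower (camera, Benjamini-Hochberg adjusted p = 0.0117; adjusted p = 0.218 with an estimated correlation). Muc13, a mucin, rose 3.32-fold and Foxj1, the regulator of ciliated cells, 2.42-fold, while Gp2, a microfold cell receptor, fell by 0.99 ± 0.20 (SE) on the log2 scale. Krt15, a keratin of basal epithelium, and Calca, a neuropeptide gene, rose 3.85-fold and 3.14-fold among 16 medullary epithelium markers (camera, Benjamini-Hochberg adjusted p = 0.0710); Calca lost its call without WT replicate 4 or KO replicate 1 or 2. Cortical epithelium had 0 of 11 markers called by edgeR (camera, Benjamini-Hochberg adjusted p = 0.752).

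Macrophage and dendritic cell markers were higher in KO, with Cd14 3.15-fold and Itgam, an integrin of myeloid cells, 2.05-fold risen and 12 not called (camera, Benjamini-Hochberg adjusted p = 9.2e-05; adjusted p = 0.339 with an estimated correlation). Their sum was 2609 ± 424 CPM in KO and 1439 ± 366 CPM in WT (SD, n = 4 each; exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0857). Thymocyte markers were not called as a list (camera, Benjamini-Hochberg adjusted p = 0.228), with Endou higher and Themis and Tox lower; Itgam, Themis and Tox lost their calls without any of 7, 6 and 8 libraries. Lists for B cells, innate lymphoid cells, fibroblasts and endothelium were not called (camera, Benjamini-Hochberg adjusted p = 0.366, 0.0954, 0.379 and 0.136). Thymocyte markers summed to 317 ± 33.5 CPM in KO against 222 ± 41.4 CPM in WT, and endothelial markers to 126 ± 26.4 against 234 ± 65.5 CPM (SD, n = 4 each; exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0857, for each). Single genes carried much of both differences. Endou read 81.3 ± 24.9 CPM in KO against 26.1 ± 5.64 CPM in WT (SD, n = 4 each). The endothelial marker Fabp4, not called, read 29.8 ± 21.2 against 121 ± 56.7 CPM. Neither sum thus shows a change of a whole marker set. Col6a2, a collagen gene of fibroblasts, fell by 2.14 ± 0.39 (SE) on the log2 scale.

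Areg and Hbegf, ligands of the EGF receptor, rose 3.73-fold and 2.01-fold in KO among 17 thymus growth factor genes, a list that was not called (camera, Benjamini-Hochberg adjusted p = 0.895). Pmaip1, Sesn1 and Trp53inp1 rose among 23 p53 targets, and Isg20, Bst2 and Cxcl10 among 37 interferon-stimulated genes (camera, Benjamini-Hochberg adjusted p = 0.0366 for both; adjusted p = 0.415 and 0.367 with an estimated correlation). Hbegf lost its call without WT replicate 3 or 4, and Bst2 and Cxcl10 each without any of 5 libraries. The 73 ribosomal protein genes had a median log2 fold change of 0.29 with 0 called by edgeR (camera, Benjamini-Hochberg adjusted p = 9.2e-05; adjusted p = 0.445 with an estimated correlation). Lists for MHC class I, MHC class II, cell cycle, oxidative phosphorylation, glycolysis, cholesterol synthesis and the unfolded protein response were not called (camera, Benjamini-Hochberg adjusted p = 0.210, 0.895, 0.895, 0.895, 0.831, 0.616 and 0.481).

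The KO effect at 6 d and the 3 d response shared 61 genes higher in both and 11 lower in both, where independent calls would share 5.19 and 0.604, and 1 gene was called in opposite directions (Tmem45b, a membrane protein gene, chosen after its values were seen). Psca, Lcn2, Cd14 and Hspb1 were higher in both, and Gnb3, Gng13, Nrep and Lipc lower in both. Of the genes called higher at 3 d, 136 of 155 measured in both tables had a positive KO effect, and of those called lower, 33 of 40 a negative one. Across 9133 genes, which are not independent replicates, r was 0.313. No library is shared, and among the 35 ways to divide the KO and WT libraries into 4 and 4 the highest other absolute r was 0.309 (exact permutation p = 0.0286, the smallest these splits can give).

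**Figure D5:**
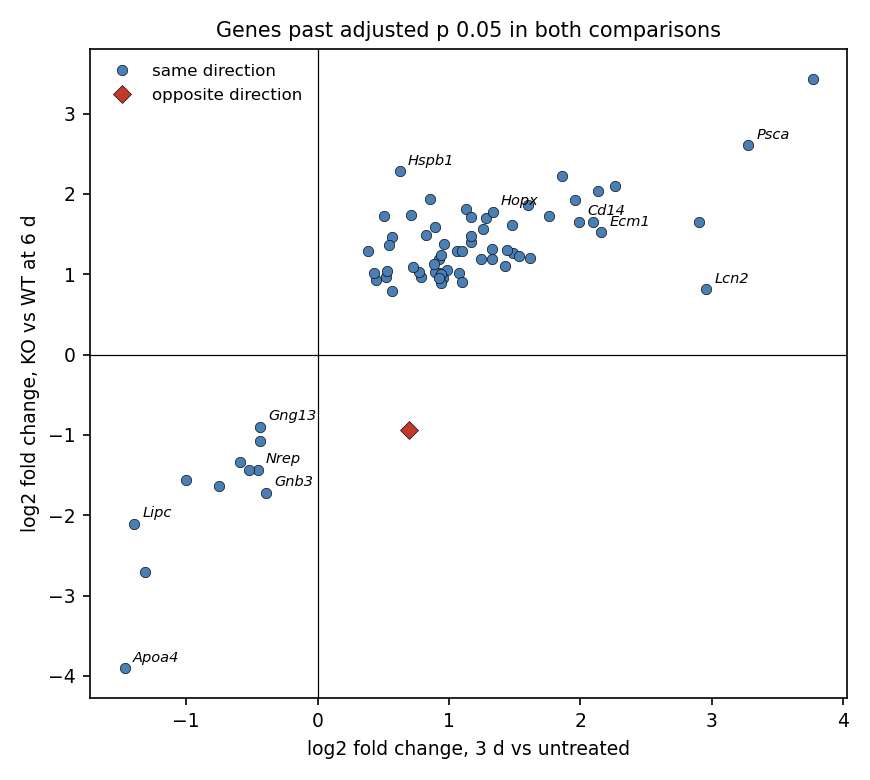
Log2 fold change at 3 d against untreated (horizontal) and in KO against WT at 6 d (vertical) for genes with an edgeR adjusted p under 0.05 in both comparisons. The diamond marks the gene changed in opposite directions.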

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

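The tests of tuft cell share, other epithelium, depth, cell stress and thymocyte RNA were chosen only after the results were seen; the counts over other splits of the libraries were planned.

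Other splits of the same libraries into groups of the same sizes tested whether chance can give as many called genes. In each comparison only the real split reached the real count, which makes chance unlikely. So few splits cannot exclude it, and at 18 h another split came close. At 18 h, 1 of 56 splits, the real one, reached 72 genes, and the highest other gave 64. That other split set untreated replicate 2 with 18 h replicates 1 and 2. At 3 d, 1 of 100 drawn splits reached 204 genes (highest other 7), between 18 h and 3 d 1 of 56 reached 73 (highest other 6), and in KO 1 of 35 reached 481 (highest other 9).

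The responses at 18 h and 3 d differed: 73 genes passed the direct edgeR test between the times. Apoa4 and Pigr were called in opposite directions against untreated, and the direct test gave a log2 fold change from 18 h to 3 d of −3.19 for Apoa4 and 2.33 for Pigr. The fall of Apoa4 at 3 d against untreated lost its call in 12 of 24 other settings, limma-voom and 9 single libraries left out among them (highest edgeR, DESeq2 or limma adjusted p 0.191, Benjamini-Hochberg).

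Single libraries lay far from the others of their group in 18 of 261 groups of values tested, where chance gives about 1 in 20, or 13.05. The 18 h group, with 3 libraries, was too small for this test and was not screened. In untreated cells, Serpina3n read 7.12 CPM in replicate 1 (others 13.3 to 16.03), Fkbp5 14.7 CPM in replicate 5 (46.4 to 64.1), summed MHC class II genes 4645 CPM in replicate 5 (6714 to 7028) and summed innate lymphoid markers 199 CPM in replicate 1 (247 to 267). At 3 d, replicate 5 had the highest Tsc22d3 (183 CPM, others 112 to 129), summed cholesterol synthesis genes (616 CPM, others 511 to 538) and summed other mimetic epithelium markers (6185 CPM, others 5219 to 5449), and the lowest Pigr (209 CPM, others 390 to 444). Summed glycolysis genes were lowest in 3 d replicate 2 (4326 CPM, others 4894 to 5026) and summed fibroblast markers highest in 3 d replicate 4 (2684 CPM, others 1725 to 1939).

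In WT at 6 d, Crnn read 36.0 CPM in replicate 2 (others 7.75 to 10.1), which also had the highest summed secreted effector genes (5825 CPM, others 5260 to 5329). Replicate 3 had the lowest Chat (2.02 CPM, others 16.4 to 22.5) and Fkbp5 (41.4 CPM, others 57.7 to 59.5). In KO, Prss53 read 8.08 CPM in replicate 4 (others 12.4 to 13.1), Pou2f3 40.4 CPM in replicate 4 (others 17.7 to 18.1), Hpgds 7.14 CPM in replicate 1 (others 21.5 to 22.9) and Tsc22d3 236 CPM in replicate 2 (others 162 to 170).

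In KO, 11 of 45 tuft identity genes were called lower, and 7 of 29 other mimetic epithelium markers higher and 2 lower; camera called both lists, but neither with an estimated correlation (Benjamini-Hochberg adjusted p = 0.0670 and 0.218), and 2 of 16 medullary and 0 of 11 cortical epithelium markers were called higher. Tuft-restricted genes were members of the tuft list, chosen after the results were seen. Left out by hand, where measured, were Krt8, Krt18, Cd24a, Vil1, Sox9, Hebp1, Espn, Nrep, Atp2a3, Ascl2 and Spib. Genes under the median level were also left out. Members shared with the taste and effector lists, such as Gnb3 and Il25, were kept. Among those dropped for their level, Hpgds had a log2 difference of 0.26, Chat of −0.73 and Tas1r3 of −1.44. All 29 tuft-restricted genes kept had a negative difference, from −1.72 (Gnb3) to −0.11 (Ltc4s), with a median of −0.61 on the log2 scale. A smaller share of tuft cells among the sorted KO cells could lower them by about the same amount: the variance of their differences was as large in 4 of 35 splits (0.138, highest other 0.228), and a scaled version was as large in 3 of 35 (24.2, highest other 35.8), so a smaller share stays open for the tuft genes. A smaller share with all other cells raised alike is argued against by 1 of 35 splits (variance of list medians 0.164, highest other 0.151; medians from −0.55 for endothelium to 0.60 for macrophages); a smaller share with a rise of a particular cell type, and loss of IL-4 and IL-13 signalling in tuft cells, stay open. After thinning to equal depth, 73.6 percent of all calls were kept in direction, which argues against lower depth of the KO libraries for most calls. The tuft and epithelial genes were not counted apart, so depth as a cause of their pattern was not tested.

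Heat-shock genes were higher after dexamethasone and in KO: of 5 chaperone genes, 5 were called higher at 18 h, 4 at 3 d and 5 in KO, and of 18 immediate early genes 1, 7 and 4. Stress during dissociation could raise both kinds. Immediate early medians were 0.28 at 18 h, 0.28 at 3 d and 0.59 in KO, and chaperone medians 0.98, 0.50 and 1.47 on the log2 scale. The gap between them, measured on log2 CPM, was as large in 1 of 56 splits at 18 h (0.73, highest other 0.50), 1 of 252 at 3 d (0.212, highest other 0.208) and 1 of 70 in KO (0.91, highest other 0.84). Since the immediate early medians were above 0, most of these genes were not called, and stress need not raise both kinds alike, dissociation stress and an effect of dexamethasone or genotype cannot be told apart: the handling of each library is not recorded.

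Of 20 thymocyte markers, 1 was called lower at 18 h and 0 at 3 d; medians were −1.82 and −1.79 on the log2 scale, and camera's list calls were lost with an estimated correlation (Benjamini-Hochberg adjusted p = 0.249 and 0.295). Their sums gave an exact permutation p of 0.125 at 18 h and 0.0397 at 3 d (Benjamini-Hochberg adjusted 0.375 and 0.0893). With both times pooled, the sum was 2.69-fold higher in untreated than in treated libraries (exact permutation p = 0.00932 over 1287 splits, not adjusted). Of 8 treated libraries, 6 lay below every untreated library. If these genes are lower, RNA of thymocytes carried over in the untreated sort could give this, and genes of 1 source in varying share would move together among libraries of the same group. Within groups the 20 markers had a mean pairwise correlation of 0.597, a value already seen in the list tests when this test was added, and 0 of 1000 random sets of like level reached it (highest 0.109). The 46 tuft identity genes also exceeded all their 1000 random sets (0.215, highest 0.0913), so carry-over and a change within the sorted cells cannot be told apart.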

How the results depend on the processing

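The fits with a thymocyte marker covariate, with 1 surrogate variable and without the libraries with the fewest UMIs were chosen only after the results were seen; the other alternatives were planned. No called gene named by the rule changed direction under any of them, but with library size alone most called genes in KO were lower instead of higher (253 of 473).

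A threshold of 2-fold left 41 genes at 18 h and 94 at 3 d, fewer by construction. At 18 h limma-voom called 44. With the thymocyte covariate 23 genes passed at 18 h and 61 at 3 d; the covariate differs between the groups, so it also removes part of the group effect. With replicate numbers as a block, 114 genes passed between 18 h and 3 d and 241 in KO; 96 passed at 18 h and 280 at 3 d. The causes of the rise from 73 to 114 and of the fall from 481 to 241 were not tested. Without each library in turn, counts ranged from 32 (without 18 h replicate 2) to 93 at 18 h, from 131 (without 3 d replicate 4) to 270 at 3 d, from 56 to 94 between 18 h and 3 d, and from 301 (without WT replicate 4) to 484 in KO. Leaving out a library also leaves fewer samples. Similarity of the 18 h and 3 d responses fell from an r of 0.472 to 0.146 once the contrasts shared no untreated library. The covariance of the log2 fold changes fell from 0.138 to a mean of 0.0582 (SD 0.0116 over 20 splits). Taking the simulated shared part of 0.0771 off the observed covariance left 0.0613, so the shared libraries can account for that fall. The split also left each contrast 2 or 3 untreated libraries instead of 5, and how far this lowered r was not tested apart.

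Other settings stayed within 1.5 times the count reported: DESeq2 gave 105, 234, 104 and 511 genes at 18 h, at 3 d, between the times and in KO, and thinned counts gave 50, 170, 63 and 390. Library size alone gave 69 (44 higher, 25 lower), 199 (131 and 68), 75 and 473 (220 and 253). In KO, 358 of those 473 were also called with TMM, all in the same direction; 1 surrogate variable gave 641.

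Of the called genes the naming rule gives, 10 of 30 at 18 h, 15 of 52 at 3 d, 13 of 29 between the times and 35 of 61 in KO passed under every setting. Among them were Serpina3n, Bag3 and Hspb1 at 18 h, Lipc, Anxa1 and Cldn4 at 3 d, Pigr and Apoa4 between the times, and Il13ra1, Gnb3 and Psca in KO. Leaving out a library ended the call of 17, 22, 15 and 16. No list call was lost or reversed by scaling with library size alone or RLE size factors. Leaving out a library ended up to 5 list calls at 18 h (without 18 h replicate 2) and at 3 d (without untreated replicate 1).

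Small changes were mostly missed: on data simulated with the depth and spread of these libraries, 1.5-fold changes were recovered for 7.46 percent of genes at 18 h, 8.96 percent at 3 d, 5.97 percent between the times and 2.99 percent in KO.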

Other observations

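No explanation was tested here, and the values across tables were set side by side only after they were seen.

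Il25 read 461 ± 138 CPM in untreated cells (SD, n = 5), 516 ± 56.7 CPM at 18 h (n = 3), 707 ± 111 CPM at 3 d (n = 5) and 1286 ± 152 CPM in WT at 6 d (n = 4). Gnb3 read 3239 ± 324, 3290.4 ± 183, 2468 ± 283 and 1791 ± 422 CPM in the same groups, and Trpm5 read 2177 ± 363, 2711 ± 181, 2497 ± 178 and 1464 ± 238 CPM. The 6 d libraries belong to a separately counted table, so no test was made between them and the time course.

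Hspb1, the most abundant gene named here in KO (13655 ± 4639 CPM, SD, n = 4), read 2803 ± 799 CPM in WT at 6 d, 2128 ± 178 CPM in untreated cells (n = 5), 4187 ± 359 CPM at 18 h (n = 3) and 3282 ± 375 CPM at 3 d (n = 5). Across 9133 genes, which are not independent replicates, the 18 h response and the KO effect correlated with r = 0.120.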
